A study of Arabidopsis thaliana with 4 samples.

How the data were processed

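Total RNA came from whole seedlings 2 weeks old, grown on plates of nutrient medium at 23 °C with 16 h of light and 8 h of dark after 4 days of stratification, per the labels' protocols. For each sample 5 µg of RNA was primed with an oligo(dT) primer, amplified by in vitro transcription, labelled with biotin and hybridised to 1 Affymetrix array, per the labels' protocols. The authors deposited 1 log2 value per probe set and array, made with MAS5 per the submitters' processing notes, with no version given. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal per array and scales each array by 1 factor. The deposited log2 values ranged from -4.25 to 14.96. Their base and scaling were read from the values: taken back to a linear scale, the mean after trimming 2% at each end lay between 495.1 and 495.6 on all 4 arrays. The scaling target is not given in the sources used here, and detection calls were not used here. Scaling by 1 factor leaves any bend in the response between arrays in place, and MAS5 signals are noisy at the dim end. A fold change from a group near the floor is therefore uncertain in size.

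Values below a linear signal of 1, between 151 and 246 per array, were set to 1 before the tests. The 9099 probe sets in the lowest 40% of the mean log2 signal over all 4 arrays were left out, which left 13647 with a mean log2 signal of 6.82 or more. The values used here held 0 Affymetrix control probe sets. Probe sets were named through the platform annotation provided: 13513 were paired with 1 gene, 503 with several and 8730 with none in that table. Of those with 1 gene, 13436 matched a gene of the TAIR10.1 assembly by Entrez ID, from which symbols, loci and neighbouring genes were taken. No genome build is given with the values, so no coordinates are printed. Among the tested probe sets 7265 were paired with 1 gene, and 1318 of the 2716 called ones.

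RECA1-OE was compared with Col-0 on the log2 values with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and no further normalization. The fit has 2 residual degrees of freedom per probe set, to which the moderation added 5.42. Reported SE are limma's moderated standard errors, and group means carry the SD of 2 arrays. The p-values rest on the spread between the 2 samples of each group, moderated by the trend over all tested probe sets. They measure no other source of variation. Fits without 1 array leave 1 array in a group, whose spread is then not measured. Without a Col-0 array the moderation gave little weight to a gene's own spread, so calls gained or kept there carry little weight. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 19 lists that had at least 4 measured members, using the brightest probe set per gene. Camera with an estimated correlation and fry were run beside it. The estimated setting rests on the 2 residual degrees of freedom, so few lists could pass it whatever their correlation. The 10 chloroplast NDH genes had an estimate of -0.04, below the preset, yet their unadjusted camera p rose from 0.025 to 0.144. The comparisons, the filter, the test and 25 gene lists were set before the data were examined. Because the annotation named few members of those lists, 16 further lists, among them the ribosomal, cell wall, P450 and conjugating enzyme lists and the parts of the chloroplast list, were fixed once the annotation had been seen and before any difference between groups was computed. Of the first 25 lists, 3 could be tested, and 8 had no named member above the filter.

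The genes named were to be RECA1, the 12 largest rises and 12 largest falls among probe sets at an adjusted p under 0.05 with groups that did not overlap and 1 paired gene, and up to 4 members of each list, by size of change among those passing and then by smallest unadjusted p. RECA1 has no paired probe set in the annotation and its place was left empty. Of the members that the list rule takes, only some are named in the text. The limma and camera steps were tested on simulated data for the 13647 probe sets in 2 and 2 arrays. Of 100 probe sets changed by 1 on the log2 scale 59% were recovered, and of 100 changed by 2, 97%, with 5 false calls. A simulation with no change gave 0 calls. Camera at the preset correlation gave p = 1.1e-23 for a shifted list and 0.115 for an unshifted one. The noise was drawn independently for each probe set, with no correlation between genes and no difference common to an array. The simulation therefore does not test calls or lists where genes correlate. Alternatives tried were quantile normalization, median centring, other filters, 16 added to each linear value before log2, the replicate number as a block, no mean-variance trend, leaving out each array in turn, an ordinary two-sample test, an adjusted p threshold of 0.1 and a 1.5-fold limit in the rule of size.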

Results

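Transcript levels were measured on 4 Affymetrix arrays in whole Arabidopsis seedlings 2 weeks old. RECA1 (AT1G79050) is a plant homologue of the bacterial recombinase RecA and is targeted to the chloroplast. The arrays held 2 samples of the wild-type ecotype Col-0 and 2 samples of T3 transgenic plants overexpressing RECA1, here called RECA1-OE, all grown without treatment. The labels call the samples of a group biological replicates, without saying whether they were grown or harvested separately. Each array gave 22746 probe sets, with a median log2 signal between 7.58 and 7.63, and 13647 probe sets were bright enough to be tested. Across those probe sets Pearson's r was 0.966 between the Col-0 arrays and 0.980 between the RECA1-OE arrays. Against RECA1-OE replicates 1 and 2 it was 0.918 and 0.924 for Col-0 replicate 1, and 0.882 and 0.884 for Col-0 replicate 2. Col-0 replicate 1 was thus nearer than Col-0 replicate 2 to each RECA1-OE array, and the reason was not tested. All of these are correlations across probe sets, which are not independent replicates. The number of arrays limits the precision of every value below.

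The design compared unstressed RECA1-OE seedlings with Col-0, asking what RECA1 overexpression does to the transcriptome. The transcription factor gene WRKY53, 4 neighbouring genes of berberine bridge enzyme-like proteins and 6 of 11 genes of CYP71B cytochromes P450 were called higher in RECA1-OE. Called lower were 19 of 69 chloroplast-encoded genes, 19 of 90 cytosolic ribosomal protein genes and 10 of 19 genes of cell wall loosening, of which 2 were called higher. These 4 lists passed camera at its preset correlation only. With an estimated correlation camera's adjusted p was 0.535 for the ribosomal list and 0.456 for the other 3. That setting rests on 2 residual degrees of freedom, so not passing it does not show that correlation between genes explains a list. By limma, 2716 probe sets differed at an adjusted p under 0.05, of which 1356 were higher and 1360 lower in RECA1-OE. Large changes leaned upward, with 174 called probe sets at least 4-fold higher and 30 at least 4-fold lower. These became 263 and 47 without Col-0 replicate 1, 236 and 61 when dim probe sets were kept, and 95 and 13 with the lowest 60% left out. A rule of size without a test, at least 2-fold apart with both arrays of a group above both of the other, took 768 higher and 385 lower probe sets, with 601 lower without Col-0 replicate 1, and the upward lean was absent at 1.5-fold, with 1590 higher and 1662 lower. The groups did not overlap in 65.0% of all tested probe sets, where 33.3% is the mean over the 3 ways to split the arrays 2 and 2. Probe sets are not independent, so any difference common to the arrays of a group would raise this share. It is a description only. The count of 2716 fell to 746 without RECA1-OE replicate 1 (485 higher, 261 lower), to 1117 without RECA1-OE replicate 2 (654 higher, 463 lower) and to 1787 when dim probe sets were kept (1035 higher, 752 lower). The rule of size took 3054 probe sets in place of 1153 when dim ones were kept, and 680 with the lowest 60% left out. An ordinary two-sample test on the same values called 0, with 2897 probe sets at an unadjusted p under 0.05 against 4824 by limma. No probe set was paired with RECA1 in the annotation used, so the transgene's own level is not analysed here and the group labels were not checked against it.

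Among single genes, the 12 named genes that rose most in RECA1-OE did so by 10.05-fold to 27.1-fold, with both RECA1-OE arrays above both Col-0 arrays. Among them were 4 neighbouring genes of berberine bridge enzyme-like proteins, a family of FAD-linked oxidoreductases. AT1G26390 rose from a log2 signal of 7.35 ± 0.09 in Col-0 to 11.57 ± 0.38 in RECA1-OE (SD, n = 2 each), which is 18.7-fold, with a limma adjusted p of 2.8e-04. AT1G26420 rose 13.8-fold, AT1G26410 12.5-fold and AT1G26380 12.2-fold, with limma adjusted p values of 0.0016, 0.0015 and 2.8e-04. WRKY53 (AT4G23810), a transcription factor of leaf senescence and defence, rose from 6.30 ± 0.63 to 9.64 ± 0.04 (SD, n = 2 each), or 10.1-fold, with a limma adjusted p of 0.0010. AT2G43620, of the chitinase family, rose 14.4-fold, from 7.31 ± 1.54 to 11.17 ± 0.26 (SD, n = 2 each), with a limma adjusted p of 0.0064, and AT1G78410, which encodes a VQ-motif protein, rose 10.9-fold. AT5G52760 and AT5G52750, both encoding proteins with a heavy-metal-associated domain, rose 18.5-fold and 10.7-fold. AT3G18250 rose 10.4-fold, and AT1G68620, of the carboxylesterase family, rose 10.05-fold. The Col-0 means of WRKY53, AT1G26420, AT1G26410, AT5G52760, AT1G78410 and AT5G38910 lay below 6.82, the lowest mean signal tested, so their fold sizes are uncertain. With the lowest 60% left out, 7 of the 12 rises were still measured, and all 7 stayed called. The germin-like gene AT5G38910 had the largest estimate, 27.1-fold, from 4.82 ± 2.67 to 9.58 ± 0.74 (SD, n = 2 each), and its limma adjusted p was 0.020. That call was lost without RECA1-OE replicate 1, without RECA1-OE replicate 2 and when dim probe sets were kept, with a limma adjusted p of 0.064 in the last case. Without Col-0 replicate 1 and without Col-0 replicate 2, the rises were 7.33-fold and 100.4-fold for AT5G38910, 30.7-fold and 6.80-fold for AT2G43620, 30.9-fold and 11.1-fold for AT5G52760, and 20.98-fold and 9.03-fold for AT1G26420. Among probe sets that pair with no gene in the tables used, the largest rises, singled out after the values were seen, were 5.29 ± 0.20 and 4.62 ± 0.14 on the log2 scale (SE), and the probe set of the latter went from a mean log2 signal of 9.40 in Col-0 to 14.02 in RECA1-OE. Which gene either of them measures is not known here, and RECA1 itself is not excluded.

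In the other direction, the 12 named genes that fell most were between 4.84-fold and 24.1-fold lower, with both RECA1-OE arrays below both Col-0 arrays. AT2G19970, which encodes a protein of the same superfamily as pathogenesis-related protein PR-1, fell from 9.77 ± 0.41 to 5.18 ± 1.25 (SD, n = 2 each), or 24.1-fold, with a limma adjusted p of 0.0021. Its neighbour PR-1-LIKE (AT2G19990) was 5.33-fold lower, with a limma adjusted p of 0.0015. GH9B13 (AT4G02290), an endoglucanase of glycoside hydrolase family 9, fell from 10.68 ± 0.41 to 7.73 ± 0.40 (SD, n = 2 each), or 7.72-fold, with a limma adjusted p of 0.0011. The glutaredoxin-family gene AT2G47880 was 6.01-fold lower, the copper amine oxidase gene AT1G31690 5.11-fold and the leucine-rich repeat gene AT4G16880 4.84-fold. AT5G62340, of the invertase and pectin methylesterase inhibitor family, was 5.17-fold lower. AT1G20070, AT4G02850, AT2G15020 and AT1G13650 were 8.47-fold, 6.87-fold, 6.64-fold and 5.10-fold lower. Except for GH9B13, AT1G13650 and AT4G16880, the RECA1-OE means of the 12 genes lay below 6.82, so their fold sizes are uncertain. With the lowest 60% left out, 3 of the 12 falls were still measured, and all 3 stayed called. AT5G62210 was 5.21-fold lower and lost its call without RECA1-OE replicate 1, and it was 7.82-fold lower without Col-0 replicate 1 and 3.46-fold without Col-0 replicate 2. Without RECA1-OE replicate 1 and without RECA1-OE replicate 2, the falls were 44.5-fold and 13.1-fold for AT2G19970, and 13.4-fold and 5.35-fold for AT1G20070. Among the unpaired probe sets the largest falls, also singled out after the values were seen, had log2 changes of -3.33 ± 0.22 and -3.26 ± 0.23 (SE).

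**Figure D1:**
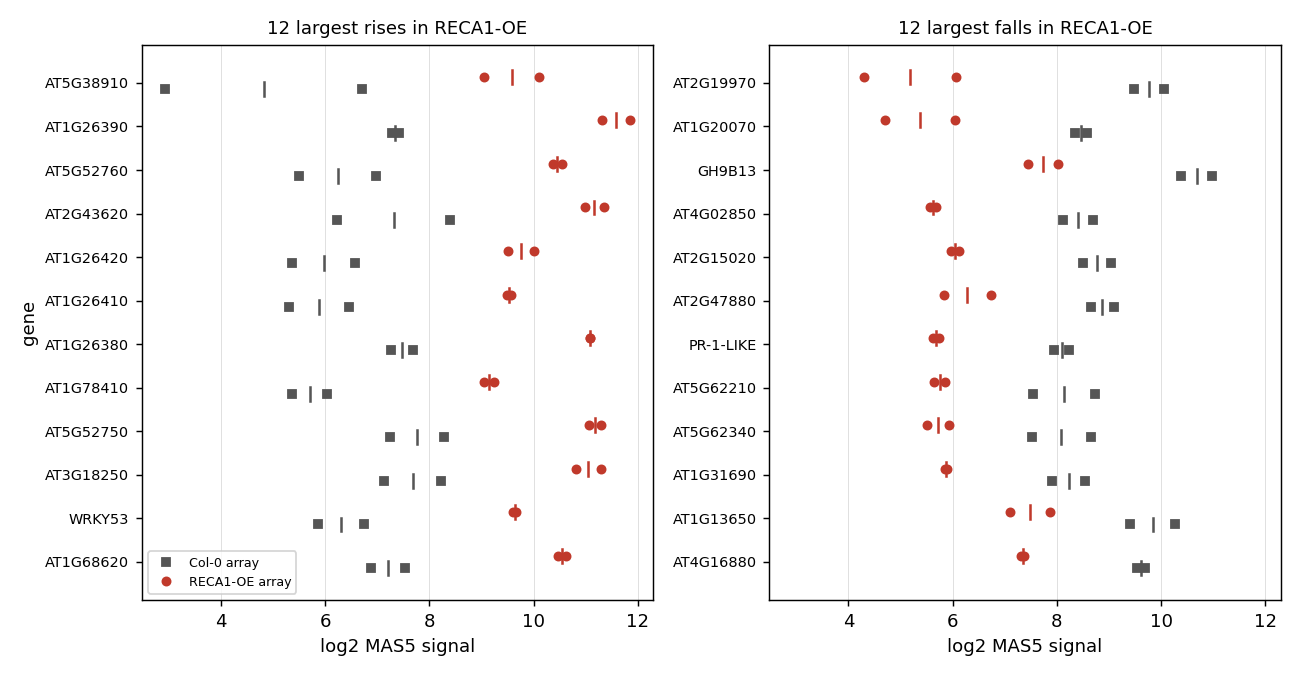
The log2 MAS5 signal of each array (x axis) is plotted for the 12 named genes that rose most (left) and the 12 that fell most (right), with Col-0 arrays as grey squares, RECA1-OE arrays as red circles and a vertical bar at each group mean (n = 2 arrays per group). The Col-0 arrays of AT5G38910 lie far apart, while those of AT1G26390 nearly coincide.

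Nearly all genes encoded in the chloroplast genome had a lower mean in RECA1-OE, and fewer of them passed. Of 69 measured chloroplast-encoded genes, 19 fell, 0 rose and 50 did not pass, and 25 fell when adjusted over the list alone. The median log2 change was -0.55, and 66 of the 69 had a lower mean in RECA1-OE, or 63 after quantile normalization. petL, a subunit of the cytochrome complex between the photosystems, fell by 1.41 ± 0.15 on the log2 scale (SE), with a limma adjusted p of 0.0017. The photosystem II genes psbD and psbB fell by 1.32 ± 0.38 and 0.95 ± 0.19, and psbK fell by 1.16 ± 0.32. ndhE, of the NAD(P)H dehydrogenase-like complex, fell by 1.12 ± 0.18, while ndhC differed by -0.47 ± 0.16 and did not pass. The plastid ribosomal protein genes rpl14, rpl16 and rps18 fell by 0.99 ± 0.20, 0.82 ± 0.16 and 0.77 ± 0.19. The list as a whole stood lower than other genes by camera, with an adjusted p of 1.3e-08 at the preset correlation and adjusted p = 0.456 with an estimated correlation. Of its parts, the 33 photosynthesis genes and the 20 plastid gene expression genes had camera adjusted p values of 2.6e-05 and 4.8e-05, each with adjusted p = 0.456 with an estimated correlation. The 10 NDH genes did not pass, with a camera adjusted p of 0.067. The 19 chloroplast-encoded calls became 4 without RECA1-OE replicate 1, 6 without RECA1-OE replicate 2 and 35 lower with 2 higher without Col-0 replicate 1. They became 8 when dim probe sets were kept and 10 without the mean-variance trend, and of the 8 falls named here only petL stayed called without each array in turn. The log2 change of psbD was -1.99 without Col-0 replicate 1 and -0.65 without Col-0 replicate 2, where that of psbK was -0.68. The calls gained without Col-0 replicate 1 carry little weight, since that fit gave little weight to a gene's own spread.

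Nuclear genes of photosynthesis were measured in small numbers. PRK, the phosphoribulokinase of the Calvin cycle, fell by 0.56 ± 0.13 on the log2 scale (SE), while SBPASE at -0.50 ± 0.16 and RCA at -0.07 ± 0.15 did not pass. In chlorophyll synthesis PORB and HEMB1 fell by 0.57 ± 0.14 and 0.55 ± 0.14, and CHLM at -0.45 ± 0.17 did not pass. Adjusted over the list alone, 2 of 3 Calvin cycle genes and 3 of 3 chlorophyll synthesis genes fell. None of 3 photosystem and antenna genes passed limma's test, and 0 had an unadjusted p under 0.05. LHCB4.1 differed by -0.19 ± 0.14, PSAN by -0.20 ± 0.14 and PSAE-1 by -0.09 ± 0.14, and after quantile normalization PSAE-1 and RCA had a positive sign. The calls of PRK, PORB and HEMB1 were lost when dim probe sets were kept, without the mean-variance trend and without RECA1-OE replicate 1. Without Col-0 replicate 1, 2 of the 3 Calvin cycle genes fell. Without Col-0 replicate 2 PRK and PORB lost the call, without Col-0 replicate 1 HEMB1, and without RECA1-OE replicate 2 PORB and HEMB1.

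Genes for proteins of the cytosolic ribosome mostly had a slightly lower mean in RECA1-OE, and fewer of them passed. Of 90 measured genes, 19 fell, 0 rose and 71 did not pass, and 27 fell when adjusted over the list alone. The median log2 change was -0.34, and 84 of the 90 had a lower mean in RECA1-OE, or 82 after quantile normalization. AT5G48760 fell by 0.74 ± 0.18, AT5G60670 by 0.72 ± 0.20 and AT3G05560 by 0.67 ± 0.15 on the log2 scale (SE). By camera the list had an adjusted p of 4.3e-08 at the preset correlation and adjusted p = 0.535 with an estimated correlation. Its estimated correlation was 0.19, against the preset 0.01 and an estimate of 0.032 for the chloroplast-encoded list. The p at the preset is therefore likely too small for the ribosomal list. The 19 calls became 1 without Col-0 replicate 2, 5 without RECA1-OE replicate 2 and, by limma, 0 without RECA1-OE replicate 1, where 24 had an unadjusted p under 0.05 and the log2 change of AT5G60670 was -0.43. They also became 9 after quantile normalization, 1 when dim probe sets were kept and 3 without the mean-variance trend.

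Genes of cell wall loosening and remodelling, a list of expansins, xyloglucan endotransglucosylases and family 9 endoglucanases, were mostly lower where called. Of 19 measured genes, 10 fell, 2 rose and 7 did not pass, and over the list alone 11 fell and 2 rose. Besides GH9B13, the endoglucanase gene GH9C2 fell by 1.47 ± 0.16 and the expansin gene EXPA8 by 1.44 ± 0.18 on the log2 scale (SE), with limma adjusted p values of 0.0017 and 0.0029. XTH18, a xyloglucan endotransglucosylase gene, rose by 1.70 ± 0.18, with a limma adjusted p of 0.0017. The list's median log2 change was -0.79. Its camera adjusted p was 0.0050 at the preset correlation, 0.119 when dim probe sets were kept and adjusted p = 0.456 with an estimated correlation. The 10 falls became 5 without RECA1-OE replicate 2 and 6 of 42 when dim probe sets were kept, and the 2 rises became 1 there, with the lowest 60% left out and whenever a RECA1-OE array was left out.

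Genes of CYP71B cytochromes P450, a subfamily of monooxygenases of secondary metabolism, were higher in RECA1-OE wherever called. Of 11 measured genes, 6 rose, 0 fell and 5 did not pass, and 7 rose when adjusted over the list alone. CYP71B23 rose by 2.46 ± 0.31 and CYP71B6 by 1.87 ± 0.19 on the log2 scale (SE), with limma adjusted p values of 0.0031 and 0.0016. CYP71B5 and CYP71B29 each rose by 1.00, with SE of 0.18 and 0.21. The list's median log2 change was 0.88, and its camera adjusted p was 0.0062 at the preset correlation, 0.055 with the lowest 60% of probe sets left out and adjusted p = 0.456 with an estimated correlation. The 6 rises became 2 without RECA1-OE replicate 1, 3 without RECA1-OE replicate 2 and 3 of 7 with the lowest 60% left out.

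Genes of conjugating enzymes changed in both directions. Of 25 UDP-glycosyltransferase genes, 9 rose, 4 fell and 12 did not pass, and over the list alone 9 rose and 5 fell. UGT73B4, UGT87A2 and UGT76B1 rose by 2.07 ± 0.34, 1.66 ± 0.17 and 1.21 ± 0.16 on the log2 scale (SE), and UGT71C1 fell by 1.25 ± 0.26. Of 9 glutathione transferase genes, 1 rose, 3 fell and 5 did not pass, and over the list alone 2 rose and 4 fell. GSTU20 fell by 1.94 ± 0.15, with a limma adjusted p of 6.9e-04, GSTF4 by 1.09 ± 0.28 and GSTU18 by 0.65 ± 0.16, whereas GSTU22 rose by 1.56 ± 0.35. The Col-0 mean of UGT73B4 (6.51) and the RECA1-OE means of UGT71C1 (6.34) and GSTF4 (6.32) lay below 6.82, the lowest mean signal tested. The sizes of these changes are therefore uncertain. Neither list passed, with camera adjusted p values of 0.276 and 0.587. Leaving out either RECA1-OE array left 2 rises and 0 falls among the glycosyltransferases and 0 rises and 1 fall among the glutathione transferases; without Col-0 replicate 2 the glycosyltransferase falls were 2, and without either Col-0 array the glutathione transferase rises were 2. The log2 change of GSTU22 was 0.96 without Col-0 replicate 1 and 2.16 without Col-0 replicate 2. When dim probe sets were kept, 4 glycosyltransferase genes rose and 2 fell, and 0 glutathione transferase genes rose and 2 fell, while with the lowest 60% left out 6 of 16 glycosyltransferase genes rose and 1 fell.

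**Figure D2:**
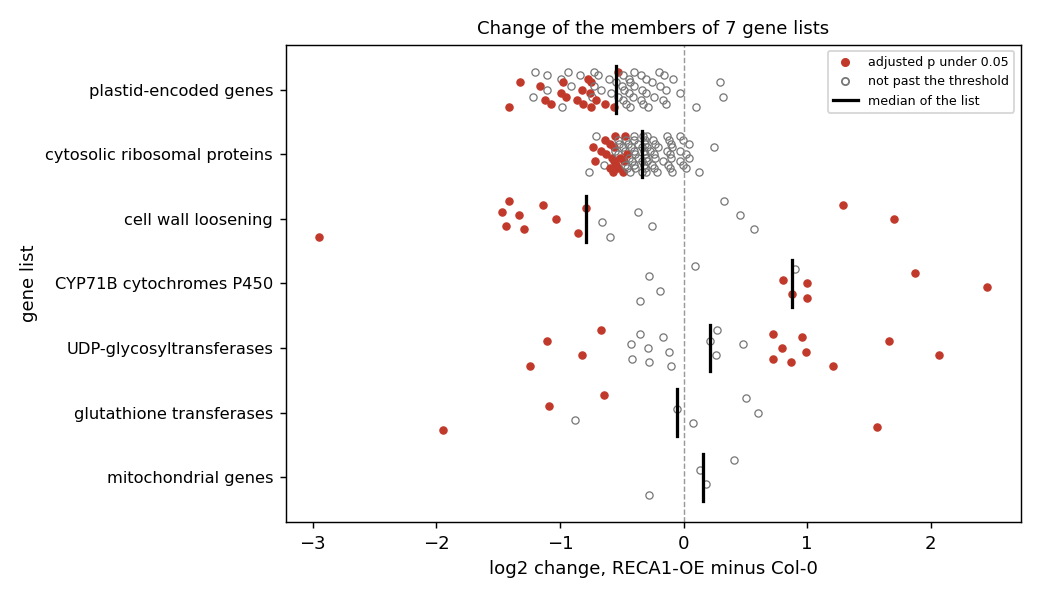
The log2 change from Col-0 to RECA1-OE (x axis) is plotted for each measured member of 7 gene lists, with filled red circles for members at an adjusted p under 0.05, open circles for the others and a black bar at each list's median. The medians of the chloroplast-encoded, cytosolic ribosomal and cell wall lists lie at -0.55, -0.34 and -0.79, and that of the CYP71B list at 0.88; vertical scatter within a list has no meaning.

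Single genes of stress, hormone and growth pathways changed as well, on lists of which few members were measured. GRX480, a glutaredoxin gene of the salicylic acid response, rose by 2.00 ± 0.23 on the log2 scale (SE), with a limma adjusted p of 0.0021. It was the 1 measured gene of the 18 loci on its list. Its Col-0 mean of 5.91 lay below 6.82, the lowest mean signal tested, so the size of its rise is uncertain. BCAT4, the aminotransferase that starts methionine-derived glucosinolate synthesis, fell by 2.14 ± 0.21, with a limma adjusted p of 0.0015. The dehydrin gene LTI30 fell by 1.39 ± 0.19 and was the 1 call among 4 cold and abscisic acid genes. Of 5 reactive oxygen genes, the zinc-finger gene STZ rose by 1.51 ± 0.27 and TAPX, the thylakoid ascorbate peroxidase, fell by 1.03 ± 0.16. Both measured cell cycle genes fell, PRL (the replication licensing factor PROLIFERA) by 1.15 ± 0.17 and AUR1 (an Aurora kinase) by 0.99 ± 0.21. The defensin gene PDF1.2 differed by 1.61 ± 0.69 and did not pass. The counts on these lists were the same when adjusted over the list alone. STZ and AUR1 lost their calls when either RECA1-OE array was left out, and TAPX without RECA1-OE replicate 2. The fits without a Col-0 array gave little weight to a gene's own spread, so calls gained there are not counted. The Col-0 arrays of the cold gene COR15A lay at 8.42 and 11.37, on both sides of its RECA1-OE mean of 9.04. The log2 change of PDF1.2 was 2.68 without Col-0 replicate 1, 0.53 without Col-0 replicate 2 and 0.88 without RECA1-OE replicate 1.

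Lists close to the function of RECA1 and lists of other organs gave no calls, but few of their members were measured. Measured were 3 of 19 organelle DNA maintenance loci, 1 of 20 nuclear DNA damage loci, 0 of 15 plastid transcription machinery loci and 2 of 9 root markers. Of 3 organelle DNA maintenance genes none passed limma's test over all probe sets, 1 had an unadjusted p under 0.05, and 1 was lower when adjusted over the list alone. DRT100 differed by -0.44 ± 0.14 on the log2 scale (SE) and OSB1 by -0.26 ± 0.23. ATLIG4, the 1 measured gene of the nuclear DNA damage list, differed by 0.22 ± 0.23, and 0 of 3 measured neighbours of RECA1 passed or had an unadjusted p under 0.05, with AT1G79080 at -0.27 ± 0.19. The root markers EXPA18 and PYK10 differed by -0.66 ± 0.28 and -0.43 ± 0.24 and did not pass by limma, with 1 at an unadjusted p under 0.05. Their log2 changes were -1.01 and -0.73 without Col-0 replicate 2, and -0.30 and -0.13 without Col-0 replicate 1. Adjusted over the list alone, 0 genes of the DNA damage, neighbour and root lists passed. No flower or seed marker of the lists was paired with a probe set in the annotation used.

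Of 19 lists tested with camera, 6 passed at the preset correlation, and 0 passed with an estimated correlation, where 1 had an unadjusted p under 0.05. Fry, which asks whether a list's genes move on balance one way, passed 0 lists after adjustment and 9 at an unadjusted p under 0.05, with a smallest adjusted p of 0.070. Among the 13 lists that did not pass, 1 of 9 genes of ATG8 autophagy proteins rose, ATG8B by 1.09 ± 0.15 on the log2 scale (SE), and 1 of 6 RALF-like peptide genes, RALFL33 by 1.07 ± 0.15. Of 10 ubiquitin-conjugating enzyme genes UBC32 and UBC30 rose, and over the list alone 2 rose and 1 fell. SWEET17 fell by 1.09 ± 0.19 and SWEET11 rose by 0.85 ± 0.23 among 6 sugar transporter genes. Of 10 beta-glucosidase genes BGLU46 rose while BGLU40 and BGLU33 fell, and of 14 serine carboxypeptidase-like genes SCPL34 rose while scpl31 and scpl20 fell. AGL87 fell by 0.99 ± 0.19 among 4 AGAMOUS-like genes, where 1 rose and 1 fell over the list alone. None of 4 mitochondrial genes passed limma's test or had an unadjusted p under 0.05, with cox1 at 0.40 ± 0.18 and nad4 at -0.28 ± 0.15. Of the calls in this paragraph, those of ATG8B and RALFL33 held without each array in turn, while each of the others was lost without RECA1-OE replicate 1 or RECA1-OE replicate 2, and SWEET11 also without Col-0 replicate 2, where its log2 change was 0.49. Without Col-0 replicate 1, 3 ATG8 genes and 2 beta-glucosidase genes rose and 1 ubiquitin-conjugating enzyme gene fell. That last fall also came with median centring and with the lowest 60% left out, where 1 serine carboxypeptidase-like gene fell. When dim probe sets were kept, SWEET11 and BGLU33 lost their calls and 1 RALF-like gene fell; without the mean-variance trend SWEET11 lost its call and 1 AGAMOUS-like gene rose. The median and mean of a list differed in sign for the sugar transporters (0.14 and -0.03, camera upward), the RALF-like peptides (-0.01 and 0.09, camera upward) and the beta-glucosidases (-0.07 and 0.09, camera downward).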

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

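The alternatives below were set before the data were examined. Signal over background limits the dim genes, since no detection calls were used here. The count of 2716 called probe sets stayed within 1.5 times under quantile normalization, median centring, an added 16, the stricter filter, no trend and an adjusted p of 0.10, and became 1787 with no filter. The ordinary two-sample test, which has 2 degrees of freedom and no moderation, called 0, with 2897 at an unadjusted p under 0.05. Without single arrays the limma count ran from 746 to 3906, the lone array being assumed to vary like the other group. The 746 came without RECA1-OE replicate 1 and the 3906 without Col-0 replicate 1. Without a Col-0 array the fit gave little weight to a gene's own spread, so the 3906 carries little weight. The 1153 probe sets of the rule of size became 3054 with no filter, 680 with the lowest 60% left out and 3252 at 1.5-fold, as the rule's construction implies, and ran from 1032 to 1563 without single arrays. The replicate number as a block gave 2390 calls, 1157 probe sets by the rule of size (same direction in both pairs) and 7 lists. The deviations of same-numbered arrays correlated at -0.06. With only 2 pairs this cannot tell whether same-numbered arrays were grown or harvested together, and the labels give them only a shared number. Of 19 lists, 6 passed at the preset correlation, 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 0 by fry (9 at an unadjusted p under 0.05). The chloroplast-encoded, cell wall and CYP71B lists had adjusted p = 0.456 with an estimated correlation and 0.070 by fry, and the ribosomal list 0.535 and 0.079. The cell wall list had a camera adjusted p of 0.119 with no filter and the CYP71B list 0.055 with the lowest 60% left out; the cause was not tested. Without single arrays the lists were tested by camera at the preset correlation only, so those tests do not answer the result with an estimated correlation. The median log2 changes there ran from -0.60 to -0.46 for the chloroplast-encoded list and from -0.42 to -0.30 for the ribosomal list. For the cell wall list they ran from -0.91 to -0.69, and for the CYP71B list from 0.69 to 0.92. Directions turned, with no call on either side and the cause not tested, for the SWEET list (camera adjusted p of 0.893 with no filter, 0.920 with the stricter filter, 0.639 to 0.924 without single arrays, 0.735 by fry) and the beta-glucosidase list (0.436 to 0.998 without single arrays). The log2 changes of PSAE-1 and RCA were 0.069 and 0.021 after quantile normalization and ranged from -0.22 to 0.047 and -0.25 to 0.10 without single arrays, and that of GI from -0.21 to 0.0031. Of 73 called genes named, 0 turned direction in any setting, 58 stayed called in every limma setting with all 4 arrays and no block in which they were measured (51 were measured with the lowest 60% left out), 69 under the block and 37 without each array in turn. Calls kept without a Col-0 array carry little weight, so the 37 were tested mainly by leaving out a RECA1-OE array. That 0 called genes turned direction says little. The filters, the trend and the block leave the difference between the group means unchanged. Leaving out 1 array cannot turn a gene whose groups do not overlap, which the naming rule required of the 12 largest rises and 12 largest falls. The alternatives for RECA1 were not run because no probe set was paired with it.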

Other observations

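The families in this part were chosen after their largest changes were seen, and of the tests below only those on matched random lists for the chloroplast-encoded and ribosomal genes were written before their result was seen. Beyond the 4 neighbouring genes already described, other berberine bridge enzyme-like genes rose as well. Outside those 4 genes, 4 members were called higher and 2 lower, where 19.9% of all tested probe sets were called. The family count and median that follow include the 4 neighbouring genes, whose large rises led to the choice of the family. Of 11 measured family members 8 rose and 2 fell by limma, with a median log2 change of 2.12, and leaving out either RECA1-OE array left 7 rises and 1 fall, and 1 fell when dim probe sets were kept and with the lowest 60% left out. AT1G30700 rose 5.98-fold and AT4G20860 4.35-fold, both with a limma adjusted p of 6.6e-04, while AT5G44380 rose 2.31-fold and AT4G20830 2.15-fold. AT5G44400, which lies close to AT5G44380, was 2.37-fold lower, with a limma adjusted p of 0.0028, and AT5G44410 was 1.70-fold lower.

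AT4G12490 and AT4G12500, of a cluster of hybrid proline-rich proteins, rose 7.33-fold and 4.95-fold, with limma adjusted p values of 6.6e-04 and 6.1e-04. In a cluster of receptor kinase genes on chromosome 1, 2 of 5 measured genes rose, AT1G51890 by 6.48-fold and AT1G51790 by 2.17-fold, where 1 rose when either RECA1-OE array was left out and 1 fell without Col-0 replicate 1. The germin-like gene AT1G18980 rose 2.33-fold, besides AT5G38910, while AT3G10080 differed by -0.46 ± 0.18 on the log2 scale (SE) and did not pass, but was called lower without Col-0 replicate 1. No small auxin up RNA gene named in the annotation was bright enough to test.

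The first pattern is the lower level of chloroplast-encoded genes. The values argue against a bend of the signal scale between arrays as its whole source: the list's median of -0.55 lay below all 10000 random lists matched on mean signal (percentile 0), whose 2.5th percentile was -0.22. A lower share of green tissue or chloroplasts stays open: 9 nuclear photosynthesis genes had a median of -0.45, at percentile 0.96 of matched lists, but at 5.01 without Col-0 replicate 1 and at 17.08 without RECA1-OE replicate 2, where the median was -0.24. Poor recovery of organelle RNA, which lacks stable poly(A) tails under oligo(dT) priming, stays open, because only 4 mitochondrial genes were measured, with a median log2 change of 0.16. An effect of RECA1 on the chloroplast genome or its transcripts is the biological explanation the design offers, and it was not tested.

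The second pattern is the small fall of cytosolic ribosomal protein genes. Its median of -0.34 also lay below all 10000 matched lists (percentile 0), whose 2.5th percentile was -0.23, so the same bend is unlikely to be its whole source. The percentile was 0.01 after quantile normalization. Slower growth of RECA1-OE seedlings or a difference in their stage is a candidate explanation that was not tested.

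The third pattern is the rise of berberine bridge enzyme-like genes. Signal shared between the tandem copies on chromosome 1 does not account for the whole of it, since 4 members outside that cluster were called higher, each on a probe set without a suffix for shared probes. A different time of harvest cannot be told apart from the groups, because GI was the 1 clock gene measured, at a log2 change of -0.10. A defence-like state of the RECA1-OE plants, from the transgene, its insertion site or growth conditions that differed between the groups, may underlie the pattern and was not tested.

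The 4 arrays can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split gave 2716 calls by limma, the most of the 3, and was the 1 split with as many. The highest count of the other splits was 0, with 29 and 53 probe sets at an unadjusted p under 0.05. Each of them puts 1 Col-0 and 1 RECA1-OE array in each group, so the difference between the groups raises their residual spread. Their counts are therefore no measure of what chance alone would give.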
